A study of Homo sapiens with 19 samples.

How the data were processed

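Hi-C was carried out on flash-frozen human tissue. Per the labels' protocols, about 65 mg of pulverised tissue per experiment was fixed in 1% formaldehyde for 25 min, the chromatin was cut with HindIII, and the filled-in ends were marked with biotin before dilute ligation. Ligated DNA was sheared to about 400 bp for Illumina libraries, per the labels' protocols. HindIII recognises a short, fixed sequence, which limits the resolution of a contact map to fragments of several kilobases on average. BWA 0.7.8 and SAMtools 0.1.18 are named in the submitters' processing notes, as are the builds hg19 (human) and mm9 (mouse). The role of each in the processing is not given in the sources used here. Per the file headers, the authors' manifest lists contact matrices in raw, HiCNorm and HiCNorm_QQ forms.

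Only a manifest was used. As deposited, it names for each library the set of FIRE calls, contact matrices, domain boundaries, compartment track and Fit-Hi-C output that the library belongs to. These cells are text and hold no measurement. A second text, a list of literature references to Hi-C data of other studies, was not used. Entries of the manifest for libraries of other studies were not used, except to look up whether a code also occurs there. Contact matrices, FIRE calls, domain boundaries, compartment tracks, Fit-Hi-C output and gene expression were not analysed here.

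Libraries were grouped by their tissue label. Each row of the manifest was matched to a library by its title. A biological replicate was another donor, as the design text defines it, and libraries of the same donor and tissue were counted once. Donor labels were numbered within a tissue. Over all tissues, the donor labels and those found in 2 or more tissues were counted. The number of differently named sets per tissue and kind, and the number of set names given to 2 or more libraries or to 2 donors, were counted in Python 3.11.15. Tests of read depth, of the share of intrachromosomal and long-range read pairs, of the number of called features and of their relation to depth had been fixed before the data were examined. None of them could be run on text entries, and no statistical test is reported. The rule for naming genes applied to values per gene or region, and it named none. The lists of tissue genes fixed beforehand had no values to be scored on.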

Results

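Chromatin contacts were profiled by Hi-C in 19 libraries from 11 human tissues. Hi-C is a proximity ligation assay that pairs DNA fragments lying close together in the nucleus. The tissues were adrenal gland, bladder, dorsolateral prefrontal cortex, hippocampus, lung, ovary, pancreas, psoas muscle, right ventricle of the heart, small intestine and spleen. The series title concerns spatially active regions. The authors' manifest lists FIRE calls, which mark regions of unusually high local contact. The tables used here held the composition of the authors' result sets and no contact count, peak, domain boundary, compartment score or gene expression value. The manifest contained 0 numeric cells. Read depth per library is therefore unknown here. No level, fold change or test is given for any gene, region or cell type.

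Replication differed between the tissues. Pancreas was represented by 4 libraries, psoas muscle by 3, and bladder, lung and spleen by 2 each. The other 6 tissues had 1 library each. By the donor labels, lung, pancreas, psoas muscle and spleen each had 2 donors, so 4 of the 11 tissues had biological replicates in the sense of the design. Both bladder libraries carried the label of 1 donor and count once. The cortex and hippocampus libraries carried no donor label, so tissue and donor cannot be told apart in them. Whether they shared a donor is not given either. Counting libraries of 1 donor in 1 tissue once, and each of these 2 unlabelled libraries once, the series held 15 combinations of tissue and donor. These are not 15 independent donors. The 13 labelled combinations carried 3 donor labels, each of which recurred in more than 1 tissue, so samples of different tissues shared donors. Adrenal, bladder, ovary, right ventricle and small intestine each had 1 labelled donor, so the spread between donors within these tissues cannot be measured. By the titles, the donor of each also gave other tissues, so the design allows tissues to be compared within 1 donor. By the titles, adrenal, ovary and small intestine carried the same donor label.

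The contact matrices and the boundaries of topologically associating domains, the megabase-scale blocks within which chromatin contacts are enriched, were listed separately for each donor. The manifest named 15 sets of matrices and 15 sets of domain boundaries for the 19 libraries. In each of these kinds, 3 names were given to more than 1 library, and 0 names were given to libraries of 2 donors. The libraries that shared a name were those of bladder, of 1 pancreas donor and of 1 psoas muscle donor, and at most 3 libraries shared one. The domain boundaries of such libraries were listed as a single file. All 15 names of matrices held a wildcard that can stand for several files, so whether the matrices of these libraries were merged cannot be read from the names. Lung, pancreas, psoas muscle and spleen each had 2 sets of matrices and 2 sets of domain boundaries, 1 per donor. The matrices and boundaries themselves were not analysed here, and the spread between donors was not measured.

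The FIRE calls and the compartment tracks were listed by tissue. A compartment track assigns each region to the active A or the inactive B compartment from the leading principal component of the contact map. The manifest named 11 sets of FIRE calls and 11 compartment tracks, and in each kind 4 entries covered libraries of 2 donors: lung, pancreas, psoas muscle and spleen. As listed, a tissue with 2 donors thus had a single entry, and whether it holds values for each donor cannot be read from its name. The largest entry, that of pancreas, covered 4 libraries. The manifest does not say whether libraries were pooled before calling or how calls from 2 donors were joined.

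The output of Fit-Hi-C, a method that tests each pair of regions against the contact frequency at their distance, was listed under 11 names. All 11 names held such a wildcard as well. Whether the 2 donors of lung, pancreas, psoas muscle and spleen were kept apart in that output cannot be read from these names. Among the 19 libraries, no entry of any of the 5 kinds was shared by libraries of 2 tissues. The ovary library was listed under the code OV for its matrices, domain boundaries and Fit-Hi-C output and under the code LV, which the manifest also lists among sets of other studies, for its FIRE calls and compartment track.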

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

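The number of tissues with replicates was 4 when donors were counted and 5 when libraries were counted, the difference being bladder. With each of the 19 libraries left out in turn, an alternative chosen after seeing the data, the number of tissues with 2 donors ranged from 3 to 4. This range follows from the donor labels alone and is no test of the processing. The count fell to 3 where the library left out was the only one of its donor in a tissue with 2 donors. No paired analysis was possible because the manifest's entries hold no measurement. The design itself offers pairing, since donor labels recurred between tissues. Other settings fixed beforehand for read pairs, shares of read pairs, feature counts and their relation to depth were not run, since the table used holds no such values.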

Other observations

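In 18 of the 19 libraries, the entries of all 5 kinds carried 1 tissue code. The ovary library was the exception, with the code OV in 3 kinds and the code LV in 2 kinds, the FIRE calls and the compartment track. The code LV also occurs in the manifest's list of sets from other studies, and the code OV does not. Which FIRE calls and compartment values belong to ovary was not checked against the call sets, which were not analysed here. Ovary results taken through this manifest for those 2 kinds need that check first.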
